A study of Mus musculus with 8 samples.

How the data were processed

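The study measured poly(A) RNA in 2 mouse kidney epithelial cell lines. One line is heterozygous for Pkd1, the gene for polycystin-1, which is mutated in autosomal dominant polycystic kidney disease, and the other is null for it. Each line received DMSO, the solvent, or THZ1, a covalent inhibitor of the kinase CDK7, at 50 nM for 6 h. There were 8 libraries in 4 groups of 2. Per the labels' protocols, RNA was isolated with TRIzol and selected with oligo dT, and the libraries were made by a company. Groups and replicate numbers were taken from the labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

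Each deposited file holds 1 FPKM value per gene, that is fragments scaled by transcript length and by the mapped fragments of the library, as the authors computed it. Per the submitters' processing notes, Bowtie2 and DESeq2 were used with the mouse build mm10, with no versions given. The program that counted the fragments and made the FPKM values, the gene annotation and the handling of strand are not given in the sources used here. Each file lists 18631 genes by Entrez gene ID, with values rounded to 2 decimals. Symbols and coordinates came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 stands for. It gave a symbol for 18592 IDs and none for 39. In all libraries 1319 genes were listed at 0.

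The design had assumed read counts, and had set limma-trend on log2(value + 1) for the case that the files held normalized values. FPKM values are not counts, so that test was used. Genes with a mean FPKM of at least 1 over the 8 libraries were kept, which left 10731. The values were transformed to log2(FPKM + 1), without further scaling between libraries. A fold change is therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 8 libraries, with 4 residual degrees of freedom per gene and a prior spread that follows the mean level. p-values are two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. The comparisons were null against heterozygous cells under DMSO, THZ1 against DMSO in each line, the difference between those 2 responses (the interaction), and null against heterozygous cells under THZ1. Errors of fold changes are limma's standard errors, and those of FPKM means are SDs over n = 2.

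In all, 34 gene lists (pathways and cell type markers) were fixed with the comparisons, the named-gene rule and most alternatives before the data were examined. They hold 785 memberships of genes in the files, over 746 distinct genes. The 29 lists with at least 5 tested members were tested with camera, a test of a list against all other tested genes, with a preset correlation between genes of 0.01. p-values were adjusted over the 29 lists within a comparison. Each call was repeated with a correlation estimated from the data and with fry, a test of a list by itself. Named genes are Pkd1, Pkd2, Cdk7, Ccnh, Mnat1 and Myc in every comparison. They also include the 8 called genes with the largest increase and the 8 with the largest decrease, with a mean log2(FPKM + 1) of at least 3 and no overlap between the groups' libraries. From each called list the 3 members with the smallest adjusted p in its direction were named. For the interaction, the 5 largest values each way were named under the same limits on adjusted p and level. The limit of 3 had been set on log2 CPM and was applied to log2(FPKM + 1). Predicted genes, Rik clones, pseudogenes and rows that share a symbol were passed over. Some genes that the rule would name are not analysed here. Other genes named in the text were chosen after their values were seen, and the text says so.

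The files give no read counts, but the values of low, short genes fell on steps. At 0.06 to 0.4 FPKM and transcripts of 500 to 2500 bp, the steps corresponded to 1 fragment per 54.75 to 57.5 FPKM × bp. From this the depth was estimated at 17.4 to 18.3 M (mega) fragments per library, with bootstrap SDs of 0.22 to 0.89 M. On simulated data of 12, 18 and 25 M fragments the same method returned 12.0, 18.0 and 25.3 M. The fit was tested on simulated values with the real means and spreads in 10731 genes. Of these, 67 were changed by 0.25 on the log2 scale, 67 by 0.5 and 66 by 1. For THZ1 in null cells the fit called 47.8%, 94% and 100% of these genes in that order, with 8 false calls. For THZ1 in heterozygous cells the shares were 53.7%, 100% and 100%, with 9 false calls, and for the interaction 19.4%, 80.6% and 100%, with 12. Far more genes were called in the real comparisons, which loosens the Benjamini-Hochberg cut-off, so these shares do not measure their sensitivity.

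Alternatives were other scalings of the FPKM values (the median of ratios to the gene means, the upper quartile, and library totals), a pseudocount of 0.1, no filter, and a filter of 5 FPKM in 2 libraries. Others were a fit of the compared groups only, a replicate block, a threshold of 2-fold, and leaving out each library in turn. A correction for GC content, a robust prior, a split of the DMSO libraries of a line between comparisons and the removal of 2 libraries together were added after the data were seen. The tables were built with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and the figures with matplotlib 3.10.9. No spike-in standard is recorded in the labels, so all levels are relative to the rest of the same library.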

Results

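The series concerns metabolic reprogramming in autosomal dominant polycystic kidney disease. RNA was sequenced from a Pkd1 heterozygous and a Pkd1 null mouse kidney epithelial cell line after DMSO or 50 nM THZ1 for 6 h, with 2 libraries in each of the 4 groups. The estimated depth was 17.4 to 18.3 M fragments per library, and 14007 to 15439 genes had a value above 0. Replicates agreed closely, with Pearson's r of log2(FPKM + 1) across genes between 0.9972 and 0.9982. The median absolute difference between replicates was 0.05 to 0.07 on the log2 scale. The first principal component held 74.9% of the variance and parted the lines, and also the null THZ1 from the null DMSO libraries. The second held 21%. Null DMSO replicate 1 and null THZ1 replicate 2 had more genes just above 0 (0.01 to 0.2 FPKM) than the other libraries, 3378 and 3129 against 2230 to 2586.

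**Figure D1:**
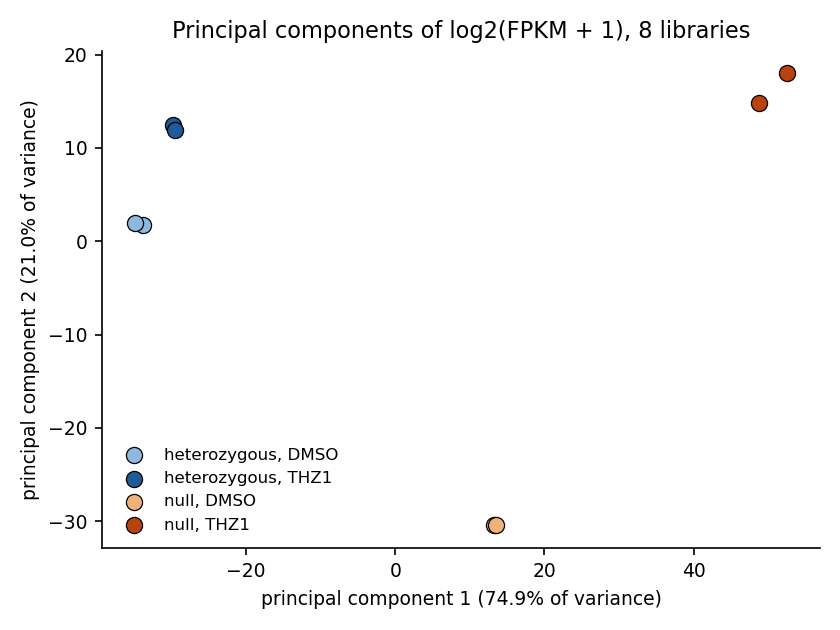
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library and colours for the 4 groups. Component 1 (74.9% of the variance) is on the x axis and component 2 (21%) on the y axis. The heterozygous libraries lie between -34.9 and -29.52 on component 1, the null DMSO libraries at 13.24 and 13.52, and the null THZ1 libraries at 48.8 and 52.54.

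The gene that defines the lines was examined first. Pkd1 (gene ID 18763, chromosome 17, 24548689 to 24596514 in GRCm38) had 4.94 ± 0.509 FPKM in heterozygous DMSO cells and 1.51 ± 0.262 in null DMSO cells (SD, n = 2 each). Under THZ1 its level was 3.96 ± 0.346 and 1.22 ± 0.00707 FPKM (SD, n = 2 each). The log2 difference between null and heterozygous cells under DMSO was -1.25 ± 0.10 (SE, limma adjusted p = 1.99e-07), so Pkd1 RNA was lower in each null library but still present. A value per gene cannot show which exons are deleted. Pkd2, which encodes the partner channel polycystin-2, was higher in null cells, at 52.5 ± 1.22 against 41.3 ± 2.67 FPKM (SD, n = 2 each; log2 difference 0.34 ± 0.05 SE, limma adjusted p = 5.02e-05).

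The first comparison asked how null cells differ from heterozygous cells without the drug. With 1 cell line per genotype, loss of Pkd1 and other differences between the lines cannot be told apart here. Camera called lists of matrix and inflammatory genes higher in null cells. It called lists for cell division, DNA repair, cholesterol synthesis, the antioxidant response and several branches of metabolism lower. With an estimated correlation 0 of these lists were called. Lcn2, which encodes the iron carrier lipocalin-2, rose from 41.9 ± 1.58 to 606 ± 8.02 FPKM (log2 3.83 ± 0.06 SE), and the smooth muscle actin gene Acta2 from 7.47 ± 0.382 to 109 ± 1.76 (log2 3.69 ± 0.06). The other large increases were in Praf2 (log2 4.64), Igfbp2, an insulin-like growth factor binding protein (4.36), Cyp4a12b (3.57), Prnd (3.47), the myosin light chain gene Myl9 (3.39) and the potassium channel gene Kcnk1 (3.37). Large decreases were in Fbxo2 (-3.14), the epithelial transcription factor gene Ehf (-3.01), Inmt (-2.48), the protease inhibitor gene Spint1 (-2.47) and the kinesin gene Kif12 (-2.42). Gstt3 (-2.18) and Fgfbp1 (-2.17) were also among them. Each of these genes had a limma adjusted p of at most 5.51e-10. In all, 7508 of 10731 tested genes (70%) were called by limma, 3110 higher and 4398 lower in null cells, and 353 and 369 of them differed at least 2-fold. With median-of-ratios scaling the split was 3610 higher and 3802 lower, and with upper-quartile scaling 3637 and 3809.

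Of the 29 gene lists tested, camera called 16 for null against heterozygous cells, 6 higher and 10 lower. The TGF-beta, EMT and matrix list had 20 members higher and 3 lower of 23 (median log2 0.81, camera adjusted p = 5.48e-09; adjusted p = 0.146 with an estimated correlation), with Acta2 and the actin-binding protein gene Tagln (2.57). Of 15 fibroblast and mesenchyme markers, 11 were under the filter and 4 were tested, too few for a list test. All 4 were higher in null cells, and 2 of them, Acta2 and Tagln, belong to the matrix list as well. The other 2 were Col1a1 (2.14 ± 0.07 SE, limma adjusted p = 9.803e-11) and Postn (0.36 ± 0.08, limma adjusted p = 0.001268). The NF-kB and inflammatory list had 17 members higher and 2 lower of 20 (median 0.68, camera adjusted p = 8.78e-06; adjusted p = 0.146 with an estimated correlation), with Lcn2, the NF-kB inhibitor gene Tnfaip3 (1.93) and the cytokine gene Csf1 (1.34). Immediate early genes had 16 higher and 3 lower of 25, with Ier3 (1.28), Ccn1 (0.99) and Fosl1 (1.16). The p53 targets had 14 higher and 5 lower of 24, with the apoptosis genes Pmaip1 (1.74), Fas (2.09) and Perp (0.99). Interferon-stimulated genes had 15 higher and 6 lower of 24, with Gbp2 (1.21), Bst2 (0.67) and Cxcl10 (0.66). YAP/TAZ targets had 13 higher and 6 lower of 20, with Crim1 (1.03), F3 (0.94) and Ccn1. Camera adjusted p for these 4 lists was 0.00217, 0.0119, 0.0249 and 0.0249, and with an estimated correlation the adjusted p was 0.467, 0.231, 0.502 and 0.398.

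Cell division genes formed the list with the lowest camera adjusted p on the lower side. Of 40 cell cycle and mitosis genes, 37 were lower and 2 higher in null cells (median -0.87, camera adjusted p = 4.02e-10; adjusted p = 0.231 with an estimated correlation). They included the replication helicase genes Mcm3 (-1.25) and Mcm4 (-1.16) and the mitotic kinase gene Aurkb (-1.51). Of 23 DNA damage response genes 22 were lower and 0 higher (median -0.77), with Fanca (-1.29), Brca1 (-1.36) and Rad51c (-1.43). Of 23 cholesterol synthesis genes 21 were lower and 0 higher (median -0.76). They included Hmgcs1, which makes HMG-CoA (-1.32), and Cyp51 (-1.10). All 21 NRF2 targets were lower (median -0.68), with the detoxifying enzyme genes Gstm1 (-1.60), Nqo1 (-1.14) and Gsr (-0.89). For these 4 lists the adjusted p was 0.231 with an estimated correlation. Among metabolic lists, pentose phosphate and nucleotide synthesis had 19 lower and 1 higher of 24, with Pgd (-0.98), G6pdx (-0.96) and Umps (-0.99). The TCA cycle had 18 lower and 0 higher of 23, with Mdh1 (-0.76), Fh1 (-0.59) and Ogdh (-0.57). Glutamine, serine and one-carbon metabolism had 17 lower and 3 higher of 23, with Psat1 (-1.02) and Shmt1 (-1.10). Fatty acid synthesis had 13 lower and 3 higher of 20, with Scd2 (-1.05), Acsl3 (-1.16) and Elovl6 (-1.01). Ribosome biogenesis had 23 lower and 0 higher of 30, with Ncl (-0.74), Rrp1 (-0.68) and Npm1 (-0.67). Cytosolic ribosomal proteins had 24 lower and 3 higher of 34, with Rpl19 (-0.46), Rpl7 (-0.39) and Rpl23 (-0.35).

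With an estimated correlation the adjusted p of these 6 lists was 0.254, 0.329, 0.321, 0.329, 0.306 and 0.624, in the order given. Glycolysis (6 higher, 14 lower of 22; camera adjusted p = 0.15) and oxidative phosphorylation (3 higher, 17 lower of 33; camera adjusted p = 0.0887) were not called. Without heterozygous DMSO replicate 1 or null DMSO replicate 1 oxidative phosphorylation was called, at 0.0435 and 0.0272 (adjusted p over the alternatives 0.0272 to 0.217). Adjusted over the list alone, the counts of members were the same for 14 of the 16 called lists, while the TCA cycle had 19 lower and pentose phosphate and nucleotide synthesis 2 higher. The cytosolic ribosomal protein list lost its call without heterozygous DMSO replicate 2 (camera adjusted p = 0.0798) and with median-of-ratios scaling (0.104, alternatives 0.0096 to 0.104). Among the fixed genes, Ccnh (cyclin H) was higher in null cells (0.51 ± 0.07 SE, limma adjusted p = 2.56e-05), as was Myc (0.17 ± 0.05, 0.00602). Cdk7 had 0.17 ± 0.08 (limma adjusted p = 0.0764). It was called higher with median-of-ratios (0.0186), upper-quartile (0.0211) and library total scaling (0.0449), with the GC correction (0.0057) and without heterozygous DMSO replicate 1 (0.027). Mnat1, the third subunit of the CDK7 complex, had -0.14 ± 0.06 at a limma adjusted p of 0.0416, and was not called in 12 of 20 alternatives.

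**Figure D2:**
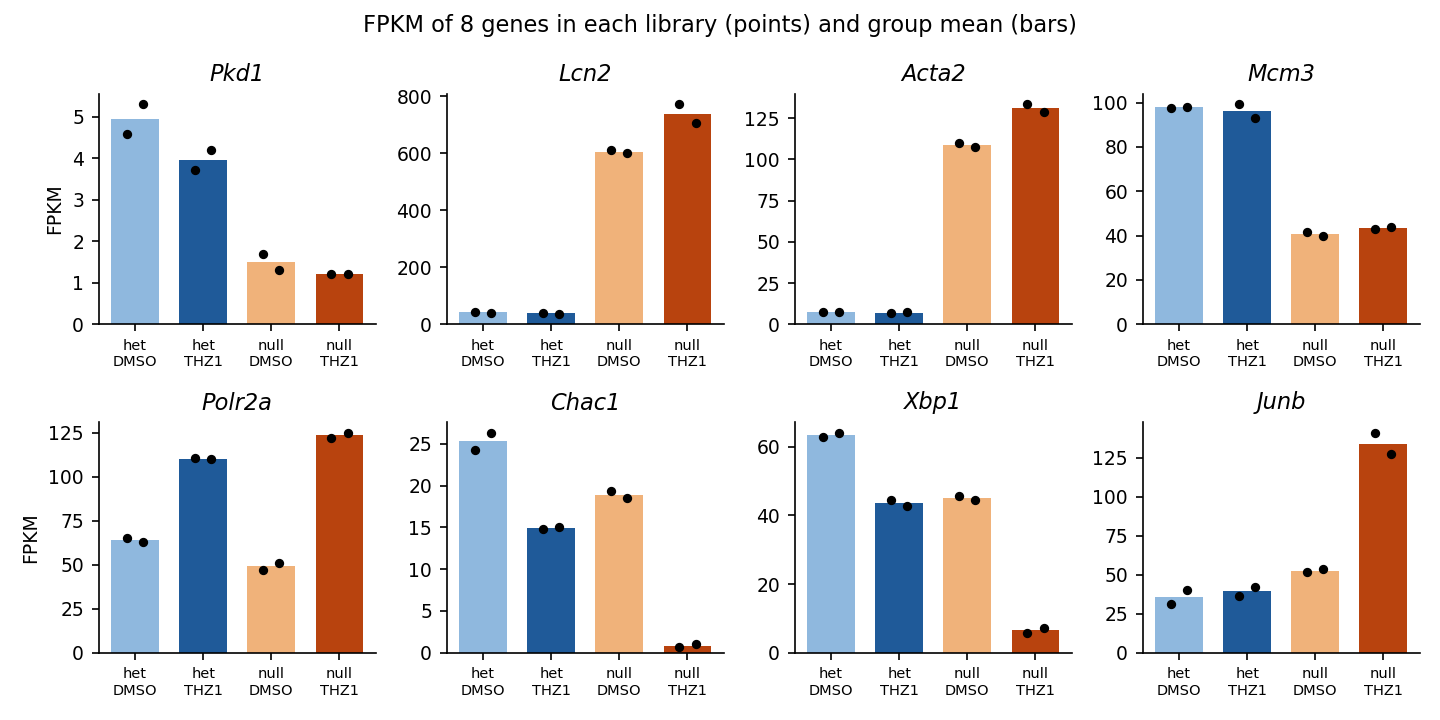
FPKM (y axis, from 0, with its own scale per gene) of 8 genes in the 4 groups (x axis). Bars are group means and points the 2 libraries of each group. Pkd1 and Mcm3 are lower and Lcn2 and Acta2 higher in null cells, Polr2a rises with THZ1 in both lines, and Chac1 and Xbp1 are lowest in null THZ1 cells, at 0.83 and 6.54 FPKM.

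The second comparison asked what THZ1 changed in heterozygous cells. The changes were small, with a median absolute log2 fold change of 0.107. In this line the median absolute difference between replicates was 0.0734 under DMSO and 0.0509 under THZ1. Polr2a, the gene of the largest RNA polymerase II subunit (gene ID 20020, chromosome 11, 69733997 to 69758633), rose from 63.9 ± 1.32 to 110 ± 0.17 FPKM (log2 0.78 ± 0.05 SE). Hexim1, an inhibitor of the elongation kinase CDK9, rose from 16.5 ± 1.13 to 28.1 ± 0.141 (0.73 ± 0.06). The other increases named by the rule were in H2ac13 (2.19 ± 0.51), Baiap2 (0.59), Pik3r3 (0.58), Taf13, a subunit of TFIID (0.56), Hacd1 (0.56) and Rnf19b (0.54). The decreases named by the rule, which passes over genes of low level, were in Krcc1, from 33.8 ± 0.113 to 16.7 ± 0.658 FPKM (-0.97 ± 0.07 SE), in the potassium channel gene Kcnj16 (-0.88), and in Ccdc9b (-0.81), Zbed6 (-0.79), the YAP target Ankrd1 (-0.74), Krt80 (-0.74), Rin1 (-0.74) and Chac1 (-0.72). The limma adjusted p of these 16 genes was at most 0.0104. In all 2406 of 10731 genes (22.4%) were called by limma, 1306 higher and 1100 lower, and 2 and 4 of them changed at least 2-fold. With scaling to library totals the split was 754 higher and 1492 lower. H2ac13 is uncertain, because it belongs to a family of near-identical histone genes and its heterozygous DMSO replicates had 25.91 and 4.03 FPKM.

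In heterozygous cells camera called 11 lists, 7 toward higher and 4 toward lower levels. Of the energy metabolism lists, oxidative phosphorylation had 15 members that rose and 0 that fell of 33 (median 0.13), fatty acid oxidation 10 and 0 of 21 (0.15), glycolysis 10 and 2 of 22 (0.15) and the TCA cycle 6 and 0 of 23 (0.10). The other 18, 11, 10 and 17 members of these 4 lists were not called. Their camera adjusted p was 1.86e-07, 0.000249, 0.00305 and 0.0032. With an estimated correlation the adjusted p was 0.405, 0.405, 0.405 and 0.413. Examples with their log2 fold changes were Ndufb8 (0.30), Ndufa1 (0.34) and Ndufa9 (0.20) of respiratory complex I. In fatty acid oxidation they were Acaa2 (0.38), Acadvl (0.29) and Hadhb (0.26), in glycolysis Gpi1 (0.24), Ldhb (0.25) and Pfkl (0.28), and in the TCA cycle Suclg1 (0.25), Pdhb (0.21) and Idh2 (0.21). Cytosolic ribosomal proteins (6 rose, 0 fell of 34) included Rps18 (0.19), Rplp1 (0.19) and Rpl27 (0.16). HIF targets (7 rose, 2 fell of 20) included Ankrd37 (0.59), Fam162a (0.25) and Ldha (0.17), and CDK7 and transcription kinases (6 rose, 0 fell of 19) included Brd2 (0.49) beside Polr2a and Hexim1. For these 3 lists camera adjusted p was 0.000249, 0.0307 and 0.0185, and with an estimated correlation the adjusted p was 0.514, 0.405 and 0.405.

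On the lower side, YAP/TAZ targets had 8 members that fell and 1 that rose of 20 (median -0.12), with Ankrd1, F3 (-0.57) and Ccn1 (-0.29). NF-kB and inflammatory genes had 10 that fell and 1 that rose of 20 (-0.13), with the prostaglandin synthase gene Ptgs2 (-0.61), the chemokine gene Ccl2 (-0.51) and Tnfaip3 (-0.26). Immediate early genes had 9 that fell and 1 that rose of 25 (-0.11), with the transcription factor genes Egr1 (-0.54) and Jun (-0.46) and the antiproliferative gene Btg2 (-0.38). Ribosome biogenesis had 6 that fell and 2 that rose of 30 (-0.07), with Ddx21 (-0.26), Polr1a (-0.26) and Utp20 (-0.31). Camera adjusted p was 0.000786, 0.00227, 0.0131 and 0.0136 in that order. With an estimated correlation the adjusted p was 0.405, 0.405, 0.526 and 0.413. Adjusted over the list alone, member counts were the same for 4 of the 11 called lists. They became 18 higher for oxidative phosphorylation, 12 for fatty acid oxidation, 11 for glycolysis, 7 for the TCA cycle and 8 for HIF targets, and 10 lower and 2 higher for immediate early genes. For ribosomal proteins 1 member was left. Pkd2 (-0.33 ± 0.05 SE, limma adjusted p = 0.00126) and Myc (-0.21 ± 0.05, 0.00824) fell. Pkd1 (-0.26 ± 0.10, limma adjusted p = 0.0804), Cdk7 (-0.11 ± 0.08, 0.347), Ccnh (-0.03 ± 0.07, 0.816) and Mnat1 (-0.07 ± 0.06, 0.401) did not pass, although Pkd1 did with library totals (0.0493) and the GC correction (0.0496).

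The count of called genes in heterozygous cells rested on single libraries: it was 797 without heterozygous THZ1 replicate 1, 1060 without THZ1 replicate 2 and 1150 without DMSO replicate 1. It was 1309 with no filter on low values. Without THZ1 replicate 1, limma's adjusted p passed 0.05 for Myc (0.0867), H2ac13 (0.0528), Pfkl (0.0542), Idh2 (0.116), Ldha (0.066), Utp20 (0.0703), Rps18 (0.156), Rplp1 (0.0801) and Rpl27 (0.221). Without DMSO replicate 1 it did so for Zbed6 (0.0743), Idh2 (0.0839), Polr1a (0.065), Utp20 (0.0955), Rps18 (0.0755), Rplp1 (0.198) and Rpl27 (0.162), and without THZ1 replicate 2 for Zbed6 (0.0523), Polr1a (0.0598), Rplp1 (0.158) and Rpl27 (0.0578). The immediate early list lost its call without THZ1 replicate 1 (camera adjusted p = 0.136) and without DMSO replicate 2 (0.192, alternatives 0.000192 to 0.192), where its median was 0.01 and 0.04 instead of -0.11. Zbed6 had -0.46 without DMSO replicate 1 and -1.11 without DMSO replicate 2. H2ac13 had 3.40 and 0.98 in these fits, and Rplp1 0.11 without DMSO replicate 1. Lists called only with a library left out were the integrated stress and unfolded protein response without DMSO replicate 1 (lower, camera adjusted p = 0.0344) and, without DMSO replicate 2, pentose phosphate and nucleotide synthesis (higher, 0.0477) and DNA damage response (lower, 0.0486). Glutamine, serine and one-carbon metabolism was called higher without DMSO replicate 2 (0.0477) or THZ1 replicate 2 (0.0241). HIF targets lost theirs without THZ1 replicate 1 (0.091, alternatives 0.0135 to 0.091).

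**Figure D3:**
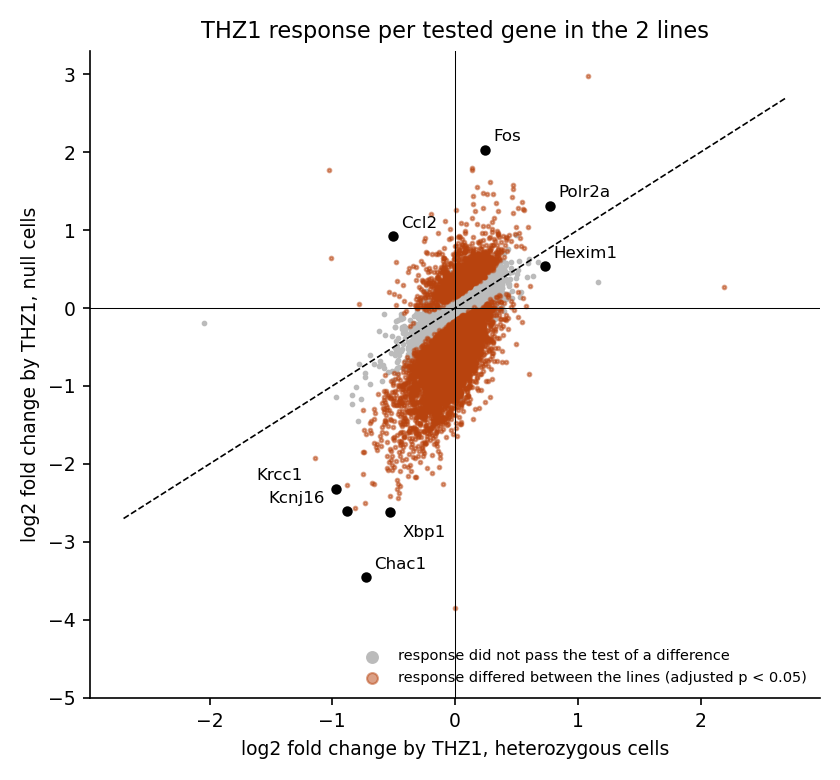
Log2 fold change by THZ1 of each of the 10731 tested genes in heterozygous cells (x axis) and in null cells (y axis). Red points are the 6463 genes whose response differed between the lines at an adjusted p below 0.05, grey points are the other genes, and the dashed line marks equal responses. Chac1, Xbp1 and Kcnj16 lie far below that line, with -3.45, -2.62 and -2.60 in null cells.

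The third comparison asked the same of null cells, where the response was larger. Above the level set for named genes, the steepest falls were in the stress response genes Chac1, a glutathione-degrading enzyme (gene ID 69065, chromosome 2, 119351242 to 119354326), and Xbp1, a transcription factor of the unfolded protein response (gene ID 22433, chromosome 11, 5520641 to 5525993). Chac1 fell from 18.9 ± 0.537 to 0.83 ± 0.255 FPKM (log2 -3.45 ± 0.09 SE) and Xbp1 from 45 ± 0.813 to 6.54 ± 1.07 (-2.62 ± 0.07). Kcnj16 (-2.60), Ccdc9b (-2.57), Rin1 (-2.50), Lrrc14 (-2.44), Eya2 (-2.32) and Krcc1 (-2.32) followed. The integrated stress and unfolded protein response list, which holds Chac1 and Xbp1, had 12 members that fell and 5 that rose of 21. Its median was -0.25, and camera did not call it (adjusted p = 0.488, fry down with adjusted p = 0.000196). Polr2a rose from 49.1 ± 2.96 to 123 ± 1.95 FPKM (1.31 ± 0.05). The other increases were in Zfp36, which encodes an mRNA decay factor (1.53), Hipk2, a kinase (1.47), Rbm14 (1.47), Dcdc2c (1.46), the adhesion molecule gene Icam1 (1.43), the AP-1 gene Junb (1.33) and Tmem245 (1.28). The limma adjusted p of these 16 genes was at most 3.37e-07. In all 8124 of 10731 genes (75.7%) were called by limma, 2645 higher and 5479 lower, with 40 and 910 of them changed at least 2-fold.

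The direction split in null cells depends on the scaling between libraries. The median log2 fold change of all tested genes was -0.173 on the FPKM values as deposited and 0.044 with median-of-ratios scaling, which gave 4488 higher and 3837 lower. With upper-quartile scaling the split was 4222 higher and 4037 lower, and with library totals 2047 and 6132. The medians of lists in null cells are therefore to be set against -0.173. The list test compares each list with the other genes of the same libraries. With no spike-in, a rise or fall under any of these scalings is relative to the other genes and not an absolute change.

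Camera called 12 lists in null cells, 10 toward higher and 2 toward lower levels. All 34 cytosolic ribosomal protein genes rose (median 0.37, camera adjusted p = 3.96e-14; adjusted p = 0.396 with an estimated correlation), among them Rplp2 (0.57), Rpl23 (0.47) and Rpl32 (0.49), and 34 rose under each scaling. Oxidative phosphorylation had 22 members that rose and 1 that fell of 33 (median 0.27, camera adjusted p = 7.96e-08; adjusted p = 0.396 with an estimated correlation), with Ndufa4 (0.61), Ndufb8 (0.52) and Ndufa1 (0.71). Glycolysis had 12 and 5 of 22, with Gpi1 (0.53), Pkm (0.56) and Ldhb (0.53). The TCA cycle had 12 and 2 of 23, with Mdh1 (0.45) and Sucla2 (0.39), and fatty acid oxidation 12 and 4 of 21, with Hadhb (0.38), Hadha (0.34) and Acaa2 (0.39). The TGF-beta, EMT and matrix list had 11 and 4 of 23, with Col4a1 (0.40), Sparc (0.37) and Tgfbr1 (0.50), and HIF targets 8 and 5 of 20, with Bnip3l (0.52), Ero1a (0.70) and Ndrg1 (0.46). The median of HIF targets was 0.06, and -0.02 with library totals, and their call ended with the GC correction (camera adjusted p = 0.0556). Camera adjusted p for these 5 lists was 0.00174, 0.00174, 0.0279, 0.0112 and 0.038, and with an estimated correlation the adjusted p was 0.396, 0.409, 0.43, 0.396 and 0.396. Of the 4 tested fibroblast and mesenchyme markers 3 rose, Col1a1 (0.51), Acta2 (0.27) and Tagln (0.20). Of the 11 tested general epithelium markers 7 fell and 1 rose (camera adjusted p = 0.405, fry down with adjusted p = 0.00591), and with median-of-ratios scaling 3 fell and 3 rose. Among the 7 were Cldn4 (-1.22), Pax2 (-0.89) and Pax8 (-0.64), chosen after their values were seen. With median-of-ratios scaling 32 members of oxidative phosphorylation rose and 0 fell. The counts were 15 and 3 for glycolysis, 21 and 1 for the TCA cycle, 16 and 3 for fatty acid oxidation, 18 and 1 for the matrix list and 15 and 3 for HIF targets.

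The 2 lists that went down in null cells were DNA damage response, with 19 members that fell and 1 that rose of 23 (median -0.48), and ribosome biogenesis, with 26 that fell and 2 that rose of 30 (median -0.41). The first included the double-strand break repair genes Nbn (-1.08), Rad51c (-1.32) and Rad50 (-1.14), and the second Tsr1 (-0.98), Ddx21 (-0.51) and Wdr12 (-0.88). Camera adjusted p was 0.022 and 0.0268, and with an estimated correlation the adjusted p was 0.43 for both. With median-of-ratios scaling 14 members of the first fell and 2 rose, and 16 of the second fell and 6 rose, and the second was no longer called (0.126, alternatives 0.0133 to 0.126). Cell cycle and mitosis genes had 27 members that fell and 4 that rose of 40 (median -0.28, camera adjusted p = 0.0687), and cholesterol synthesis 17 and 2 of 23 (median -0.33, camera adjusted p = 0.0741), and neither list was called. Their adjusted p was 0.625 with an estimated correlation. The cell cycle list was called lower with library totals (0.0464), without null THZ1 replicate 2 (0.0367) and without 2 libraries (0.0437). With median-of-ratios scaling 18 of its members fell and 13 rose, and 8 and 6 of the cholesterol list. NRF2 targets were called higher without null THZ1 replicate 2 (0.0454) and without 2 libraries (0.0377), and fatty acid synthesis without null DMSO replicate 2 (0.0434). The 3 other called lists had members that went both ways. CDK7 and transcription kinases had 10 members that rose and 8 that fell of 19 (camera adjusted p = 0.0418), immediate early genes 12 and 8 of 25 (0.04) and p53 targets 12 and 9 of 24 (0.0418). Members that rose were Polr2a, Supt5 (0.51) and Hexim1 (0.53) in the first. In the second they were Fos (from 1.96 ± 0.148 to 11.2 ± 2.23 FPKM, log2 2.03), Junb and Zfp36, and in the third Perp (0.79), Ckap2 (0.47) and the cell cycle inhibitor gene Cdkn1a (0.42). With an estimated correlation the adjusted p of these 3 was 0.396, 0.625 and 0.396.

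With median-of-ratios scaling 12 members of the kinase list rose and 3 fell, 17 and 6 of the immediate early genes, and 16 and 4 of the p53 targets. For immediate early genes in null cells the median (0.16) and mean (0.08) were above 0, while fry gave a net direction of down (adjusted p = 0.9). For p53 targets the median was 0.16 and the mean -0.02, with fry down (adjusted p = 0.0669). Both lists and the kinase list lost their calls with median-of-ratios scaling, at 0.137, 0.0541 and 0.0541 (alternatives 0.0133 to 0.137, 0.0355 to 0.0715 and 0.035 to 0.0715). Immediate early genes also did so without null THZ1 replicate 1 (0.103), heterozygous DMSO replicate 1 (0.0581) or 2 (0.0584), or heterozygous THZ1 replicate 1 (0.0593) or 2 (0.0595). The p53 targets did so without null DMSO replicate 1 (0.0532) or null THZ1 replicate 1 (0.0561). Adjusted over the list alone, member counts were the same for 10 of the 12 called lists, with 13 higher for p53 targets and 4 lower for HIF targets. Among the fixed genes Pkd2 (-0.57 ± 0.05 SE), Cdk7 (-0.52 ± 0.08), Mnat1 (-0.48 ± 0.06) and Ccnh (-0.31 ± 0.07) fell in null cells, with limma adjusted p of 3.87e-07, 6.25e-05, 5.68e-06 and 0.00151. Ccnh was not called with median-of-ratios scaling (adjusted p = 0.275, the highest of its alternatives). Myc had 40.8 ± 0.516 FPKM before and 42 ± 1.44 after THZ1 (0.04 ± 0.05, limma adjusted p = 0.459), and -0.05 with library totals. With median-of-ratios (0.28, limma adjusted p = 0.000285) and upper-quartile scaling (0.25, 0.000495) Myc was called higher, so its call depends on the scaling. Pkd1 had -0.17 ± 0.10 (limma adjusted p = 0.134), and was called without null DMSO replicate 2 (0.0479).

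**Figure D4:**
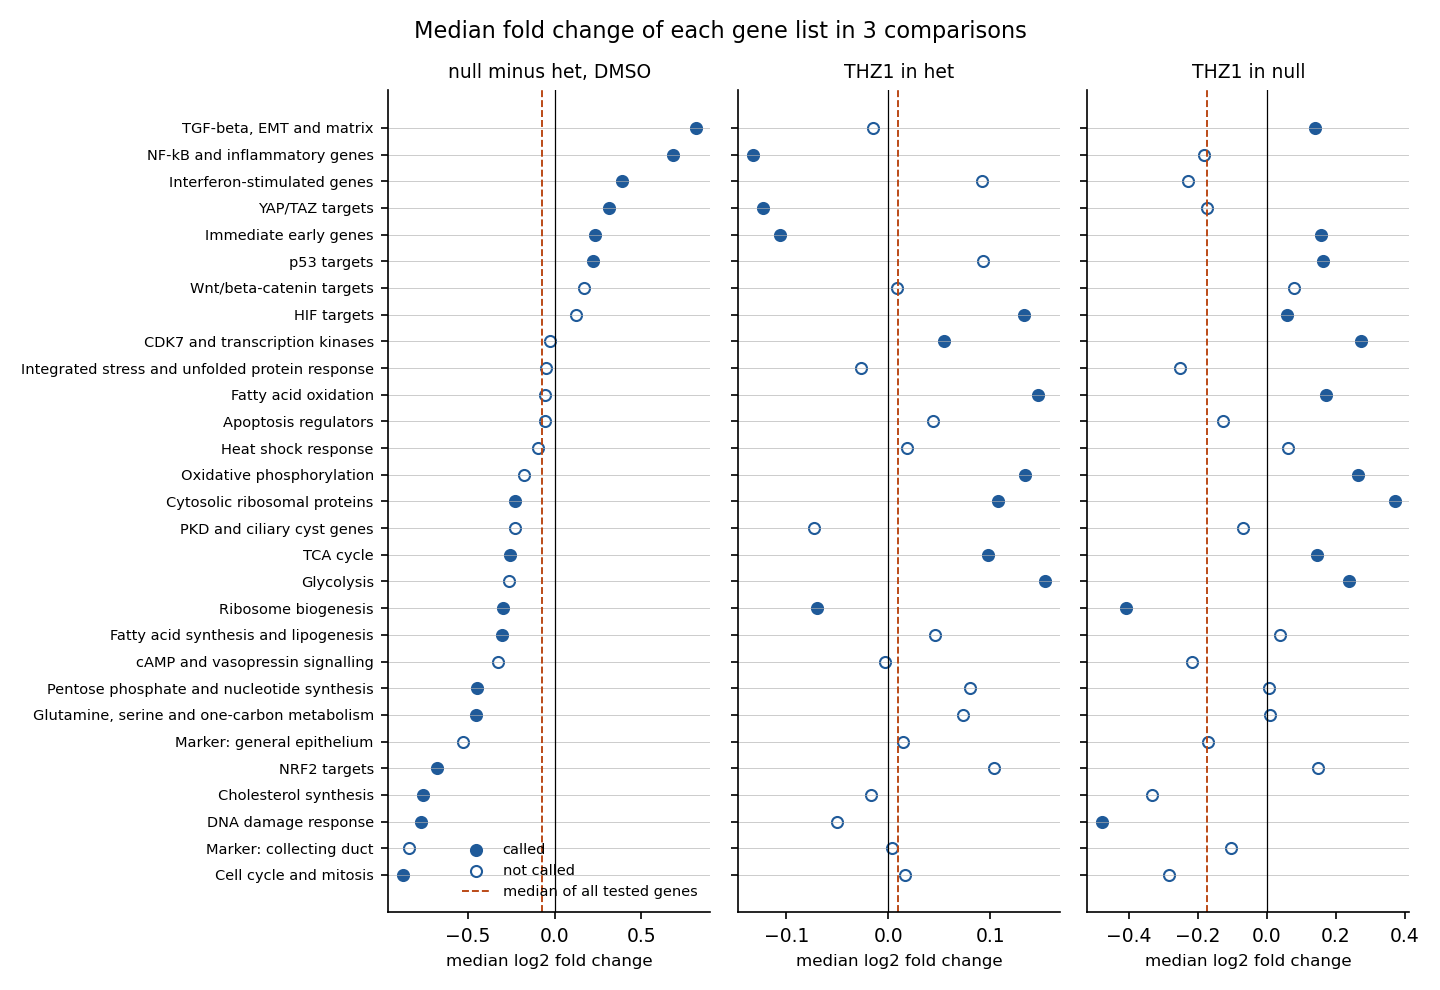
Median log2 fold change (x axis, with its own range per panel) of the tested members of each of the 29 gene lists (y axis) in 3 comparisons. Filled points are lists called by camera at an adjusted p below 0.05, open points are the other lists, and the dashed line is the median of all tested genes. Called lists number 16, 11 and 12 from left to right, and cytosolic ribosomal proteins have the highest median for THZ1 in null cells, at 0.37.

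The responses of the lines to THZ1 were then compared with each other. They went the same way for most genes called in both lines: 889 rose and 969 fell in both, 1858 together, against 883.5 for independent lists, and 177 went opposite ways, against 937.9. The 1858 became 685 without heterozygous THZ1 replicate 1, 884 without THZ1 replicate 2 and 980 without heterozygous DMSO replicate 1. With library totals 510 rose and 1326 fell in both. The responses share no library. Across genes, which are not independent replicates, the fold changes had Pearson's r = 0.595 and Spearman's rho = 0.581. Among the 1858 genes the median absolute log2 fold change was 0.262 in heterozygous and 0.564 in null cells, and 1666 changed more in null cells. Krcc1, Kcnj16, Ccdc9b, Rin1 and Chac1 were among the 8 falls named by the rule in each line, and Polr2a among the 8 increases named in each.

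The interaction tested where the responses differed, and limma called 6463 genes (60.2%), 1620 with a higher and 4843 with a lower value in null cells. With median-of-ratios scaling the split was 3539 and 3064, and with upper-quartile scaling 3389 and 3206. Of the 4843, 4593 were called lower with THZ1 in null cells, and of the 1620, 1536 were called higher there. Above the level set for named genes, the largest positive differences were in Ccl2, which fell in heterozygous cells from 113 ± 5.76 to 78.9 ± 2.26 FPKM and rose in null cells from 48.4 ± 5.94 to 92.4 ± 10.6 (interaction 1.42 ± 0.12 SE), and in Ago2 (1.40), Mical3 (1.25), Hipk2 (1.25) and Dcdc2c (1.19). The largest negative ones above that level were in Chac1 (-2.73 ± 0.12), Xbp1 (-2.08), Lrrc14 (-1.97), Arfgap1 (-1.93) and H2ac13 (-1.93 ± 0.72). The limma adjusted p was 0.0347 for H2ac13 and at most 7.37e-05 for the other 9. The call of H2ac13, uncertain as above, was lost when any 1 of 5 libraries was left out, at 0.0627 (heterozygous THZ1 replicate 1), 0.0509 (replicate 2), 0.128 (null DMSO replicate 1), 0.084 (null THZ1 replicate 1) and 0.0726 (replicate 2). Its interaction was -3.14 without heterozygous DMSO replicate 1 and -0.72 without replicate 2.

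Camera called 7 lists for the interaction. Cytosolic ribosomal proteins had 31 members higher and 0 lower of 34 (median interaction 0.28), oxidative phosphorylation 15 and 4 of 33 (0.16), immediate early genes 14 and 4 of 25 (0.25), and the TGF-beta, EMT and matrix list 10 and 3 of 23 (0.12). Glycolysis had 8 and 4 of 22 (0.07), the TCA cycle 6 and 3 of 23 (0.07) and DNA damage response 0 and 18 of 23 (-0.45). Camera adjusted p was 5.43e-14, 7.99e-05, 0.000385, 0.00104, 0.00838, 0.0327 and 0.0476 in this order, and 0.523 for each with an estimated correlation. The integrated stress and unfolded protein response list had 3 members higher and 12 lower of 21. Camera did not call it (adjusted p = 0.416, fry down with adjusted p = 0.0017). The median interaction of all genes was -0.187, and 0.031 with median-of-ratios scaling. With that scaling the members higher and lower were 34 and 0 for ribosomal proteins, 25 and 0 for oxidative phosphorylation, 17 and 4 for immediate early genes and 17 and 2 for the matrix list. They were 13 and 1 for glycolysis, 15 and 0 for the TCA cycle and 1 and 12 for DNA damage response. Adjusted over the list alone, ribosomal proteins had 33 higher, the matrix list 8 higher and DNA damage response 19 lower. The TCA cycle lost its call without heterozygous DMSO replicate 2 (0.0876), null DMSO replicate 2 (0.0561) or null THZ1 replicate 1 (0.0608). DNA damage response lost its call without these same libraries (0.0876, 0.0561 and 0.0608) and without heterozygous THZ1 replicate 1 (0.0673) or 2 (0.0527). Over the alternatives the adjusted p was 0.00199 to 0.0876 and 0.0105 to 0.0876. The cell cycle list was not called, but was called lower without heterozygous DMSO replicate 1 (0.0473), null DMSO replicate 2 (0.0494) or null THZ1 replicate 2 (0.0222), and without 2 libraries (0.0263).

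Whether THZ1 reverses the difference between the lines was tested by overlap. Of the genes higher in null cells under DMSO, 1421 fell with THZ1 in null cells and 946 rose, against 1587.9 and 766.6 for independent lists. Of the genes lower in null cells, 999 rose and 2305 fell, against 1084 and 2245.5. On the FPKM values as deposited, genes that went against the difference between the lines were thus fewer than independent lists would give, in both directions. With median-of-ratios scaling 1170 genes that were higher in null cells fell. The reverse count and the counts for independent lists were not computed with that scaling. F3 (224.3 to 122.7 FPKM) was higher in null cells and fell, whereas Lcn2, Acta2 and Junb were higher under DMSO and had still higher means under THZ1. These 4 examples were chosen after their values were seen. Both comparisons use the null DMSO libraries with opposite sign. Simulated unchanged groups, which hold no effects, gave 0 genes on average in 20 draws for the first overlap. For the genes that were lower and rose they gave 0.15. Without effects almost no gene can be called, so these counts are no yardstick for the overlaps. Across genes the correlation of the fold changes was 0.04. It was -0.496 in the simulation, where only the shared libraries link the comparisons, so these correlations cannot be compared. The covariance was 0.012 against -0.00281 in the simulation. In a split made after the result was seen, each comparison used 1 of the 2 null DMSO libraries, so that none served both. Then 1163 and 1138 genes that were higher in null cells fell, by which library was used where, against 1321.6 and 1323.2 for independent lists. Of the genes lower in null cells 810 and 809 rose, against 869.2 and 880.9. With THZ1 in heterozygous cells, 321 genes higher in null cells fell and 539 lower in null cells rose, against 318.8 and 535.3 for independent lists. These 2 comparisons share the heterozygous DMSO libraries with the same sign. The correlation of their fold changes across genes was 0.0224. The 0.498 of the simulation, which holds no effects, cannot be compared with it. The covariance was 0.00226 against 0.00282 in the simulation. Split between the comparisons in the same way, also after the result was seen, 186 and 275 genes higher in null cells fell, against 154.2 and 233.7 for independent lists. Of the genes lower in null cells 204 and 504 rose, against 217.6 and 438.9, so that this count was below in one split and above in the other. Genes higher in null cells also rose more often than independent lists would give in both splits, so the excess of falls is not particular to a reversal. The correlation was 0.0133 and -0.0436 in the 2 splits.

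Under THZ1, null cells differed from heterozygous cells in 8929 of 10731 genes (83.2%) called by limma, 2689 higher and 6240 lower. With median-of-ratios scaling the split was 4329 and 4422, and with upper-quartile scaling 4225 and 4533. Camera called 13 lists. The matrix list had 19 members higher and 2 lower of 23 (median 0.99), NF-kB and inflammatory genes 13 and 6 of 20 (0.63), immediate early genes 17 and 5 of 25 (0.42), and YAP/TAZ targets 12 and 7 of 20 (0.26). The p53 targets (11 and 7 of 24), HIF targets (9 and 7 of 20) and cytosolic ribosomal proteins (12 and 4 of 34) were called higher as well, with medians of 0.10, 0.06 and 0.03. With median-of-ratios scaling these 3 lists had 18 and 4, 12 and 2, and 30 and 0 members higher and lower, with medians of 0.38, 0.29 and 0.34. Lower were all 23 cholesterol synthesis genes (median -1.12), all 23 DNA damage response genes (-1.14) and 38 of 40 cell cycle genes (-1.19). So were 28 of 30 ribosome biogenesis genes (-0.58), 18 of 21 NRF2 targets (-0.71) and 21 of 24 pentose phosphate and nucleotide synthesis genes (-0.47). Camera adjusted p ranged up to 0.0406 over these lists, and with an estimated correlation the adjusted p was 0.14 to 0.6. Adjusted over the list alone, the member counts of all 13 were the same. With median-of-ratios scaling pentose phosphate and nucleotide synthesis (0.0651, alternatives 0.0124 to 0.0651) and YAP/TAZ targets (0.0625, 0.0112 to 0.0779) were not called. The first then had 4 members higher and 12 lower (median -0.17) and the second 13 and 6 (0.56). Without heterozygous THZ1 replicate 2, HIF targets were not called (0.0523, alternatives 0.0285 to 0.0523).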

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

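For the larger response of null cells, the comparison of replicate spreads was chosen after the result was seen. A difference between the lines in their response to THZ1, tested as the interaction by limma, marked out the following results. The response differed in 6463 genes. The named genes with a higher value in null cells were Ccl2 (log2 interaction 1.42), Ago2 (1.4), Mical3 (1.25), Hipk2 (1.25) and Dcdc2c (1.2), and those with a lower value were Chac1 (-2.73), Xbp1 (-2.08), Lrrc14 (-1.97), Arfgap1 (-1.93) and H2ac13 (-1.93). Camera called 7 gene lists for the interaction. Their median log2 interaction was 0.281 for cytosolic ribosomal proteins, 0.249 for immediate early genes, 0.161 for oxidative phosphorylation, 0.124 for the TGF-beta, EMT and matrix list, 0.07 for the TCA cycle, 0.068 for glycolysis and -0.45 for DNA damage response. Camera's adjusted p was 0.523 for each of the 7 with an estimated correlation, and the TCA cycle and DNA damage response lost their calls in 4 and 7 of 15 alternatives.

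The pattern weighed was the larger response in null cells, where the median absolute fold change was 3.18 times that in heterozygous cells. With median-of-ratios scaling 6603 genes were still called for the interaction, although the split of higher and lower values moved. With it THZ1 changed 8325 genes in null and 2203 in heterozygous cells, so scaling does not account for the larger number of calls. The ratio of 3.18 was not computed again with that scaling. A larger spread between the null libraries does not account for the larger response, since their median absolute replicate difference was 1.057 times that of the heterozygous libraries. Loss of Pkd1 and any other difference between the lines cannot be told apart, because there was 1 cell line per genotype. A difference in the uptake of THZ1 or in growth between the lines may contribute and was not tested.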

How the results depend on the processing

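The splits of the DMSO libraries, the GC correction, the robust prior and the fit without both null DMSO replicate 1 and null THZ1 replicate 2 were chosen after the data were seen. The planned DESeq2 and edgeR fits were not run, since the values are FPKM and not counts. Over the 20 alternatives, results of named genes kept their direction and side of the threshold in 3465 cases, lost the call in 163, gained it in 11 and reversed in 4. Of the losses, 103 came under the threshold of 2-fold, by construction. The reversals were Myc in null cells with library totals (-0.047), Pkd1 in null cells with the GC correction (0.107), and Ccnh in heterozygous cells without DMSO replicate 2 (0.032) or THZ1 replicate 1 (0.001), which ranged from -0.085 to 0.032 over single omitted libraries. None of these was called in either setting, and the cause was not tested.

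With no filter on low values 1309 genes were called for THZ1 in heterozygous cells and 1020 in both lines in the same direction, with 17312 genes tested. A threshold of 2-fold, which keeps only large changes by construction, left 722 genes for null against heterozygous cells under DMSO, 6 and 950 for THZ1 in heterozygous and null cells, 627 for the interaction and 1948 under THZ1. It left 44 genes that were higher in null cells and fell with THZ1, and 2 shared by the responses. With an estimated correlation 0 lists were called in each of the 5 comparisons. Fry asks whether a list moved and not whether it moved more than other genes. With it 26 lists were called for null against heterozygous cells under DMSO (8 higher and 18 lower) and 26 under THZ1 (8 and 18). For THZ1 in null cells it called 23 (9 and 14, against 10 and 2 by camera), and for the interaction 17 (2 and 15, against 6 and 1). Of the 7 interaction lists called by camera, fry did not call the TCA cycle (adjusted p = 0.352), immediate early genes (0.191), glycolysis (0.0877) or oxidative phosphorylation (0.0811). With the GC correction 7 lists were called for THZ1 in null cells, and the cause was not tested. That correction also ended the calls of interferon-stimulated genes (camera adjusted p = 0.0547) and YAP/TAZ targets (0.0559) for null against heterozygous cells under DMSO. For THZ1 in heterozygous cells it ended the call of HIF targets (0.0822). With library totals the interaction calls of the TCA cycle (0.0545) and DNA damage response (0.0676) ended.

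Each library was left out in turn, on the assumption that the lone library of a group varies like the other groups. The counts were 6679 to 7634 for null against heterozygous cells under DMSO, 797 to 2538 and 7447 to 8204 for THZ1 in heterozygous and null cells, 5682 to 6289 for the interaction, 8376 to 8982 under THZ1 and 685 to 1897 for the shared response. The cause was not tested. With the replicate number as a block (replicate block) the counts were 7502, 2387, 8112, 6461 and 8920 in the same order of comparisons, 1840 for the shared response, and 6 lists instead of 7 for the interaction, without DNA damage response (camera adjusted p = 0.0511). Deviations of samples with the same number correlated at -0.094 to 0.139, so the numbers were not shown to pair the samples. At an estimated 17.4 to 18.3 M fragments, depth limits genes of low level most, and those under a mean of 1 FPKM were not tested.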

Other observations

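The tests of depth and of receptor genes below were chosen after the result was seen, as were the single marker genes named next. Most of the epithelial markers that could be tested were lower in null cells under DMSO, and some were higher. Of 19 general epithelium markers 8 were under the filter. Of the 11 tested, 7 were lower and 3 higher (median -0.526, camera adjusted p = 0.164, fry down with adjusted p = 0.00132). Of 21 collecting duct markers 13 were under the filter. Of the 8 tested, 5 were lower and 2 higher (median -0.839, camera adjusted p = 0.268), and 4 keratin genes belong to both lists. The keratin genes Krt8 (log2 -0.81), Krt18 (-0.87) and Krt19 (-1.22) were lower in null cells and Krt7 (0.46) was higher, all called by limma. Of the collecting duct markers, Hsd11b2 (-1.75) was lower and Mal (0.97) higher. Of 16 proximal tubule markers 13 were under the filter. Of the 3 tested, Aqp1 (-1.59) and Ggt1 (-2.73) were lower while Lrp2 (1.97), which encodes the uptake receptor megalin, was higher. The kidney cadherin gene Cdh16 (0.53) was higher too. The difference between the 2 heterozygous DMSO replicates correlated with GC content (Spearman's rho = -0.458) and with gene span (0.356) across 10567 genes. For the THZ1 fold change in heterozygous cells, which uses these libraries, rho was 0.08 with GC content and -0.15 with gene span.

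Null DMSO replicate 1 and null THZ1 replicate 2 had 1.406 times as many genes between 0.01 and 0.2 FPKM as the mean of the other 6 libraries. Deeper sequencing does not account for it, since their estimated number of fragments was 0.983 times that of the others. For RNA of another tissue, abundant transcripts of liver, blood, testis, muscle, heart, brain, pancreas and leukocytes were checked. In 0 of these tissues did 2 or more reach 1 FPKM in either library while averaging below 0.1 FPKM in the other 6. Other tissues and traces under 1 FPKM cannot be excluded in this way. Genes above 0 in only 1 library had a median of 0.04 FPKM in each of these 2. Of 439 olfactory, vomeronasal and taste receptor genes, 40.77% and 32.12% had a value above 0 in these 2 libraries against 5.92% to 13.44% in the others, the lower being 3.25 times the mean of the other 6. Reads spread over the genome, such as those of genomic DNA, could give this, and no biological explanation was tested.

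Genes that fell with THZ1 in null cells included many zinc finger genes. This family was taken by symbol, as genes whose names start with Zfp and a digit, Zkscan or Zscan. It was not restricted to any type of zinc finger, and includes Zfp36, which rose. The family was not among the 34 fixed lists, and its p-values are not adjusted over lists. The family of 317 tested genes had a median log2 fold change of -0.494 against -0.173 for all genes, with 228 that fell and 32 that rose (camera p = 0.000151; p = 0.33 with an estimated correlation), and -0.311 against 0.044 with median-of-ratios scaling. Random lists matched for level, 10000 in all, had a median of -0.324, above the family's -0.494, and a lowest value of -0.5 (one-sided permutation p = 0.0002 over lists of genes). They were drawn as if genes varied independently, while the correlation estimated within the family was 0.152. This p-value therefore cannot decide whether low levels account for the falls of the family in full. Across 10567 genes, longer gene span does not account for the falls in general (Spearman's rho with the fold change 0.113). Span and GC content were not tested within the zinc finger family. The rho of the fold change with GC content was -0.084 across genes, so a steady trend with GC content was weak. The difference between the null DMSO replicates had a rho of -0.245, larger in size. The test therefore cannot tell whether GC content contributes to the falls. Fast turnover of these mRNAs could give the pattern and was not tested, and reads shared between related zinc finger genes stay open.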
